A study of Mus musculus with 6 samples.

How the data were processed

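Messenger RNA of mouse embryonic fibroblasts was sequenced in 3 wild-type and 3 Stc1 knockout libraries. Per the submitters' processing notes the tools were CASAVA 1.8.2, TopHat2 2.0.6 and Cuffdiff 2.0.1 with the mm10 build; the notes give no role or order for them. Per the file headers, each library's file gives for each locus the estimated count of fragments, the FPKM and a status. These expected counts were made by the authors and are not whole for about 24% of the values above 0, so they were rounded to whole numbers before testing. FPKM values as deposited are fragments scaled by transcript length and library size. The authors' deposited comparison table gives a mean FPKM per genotype, a log2 fold change of knockout over wild type, a p-value and a q-value for each gene; some of its fold changes are infinite and carry a placeholder.

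The files hold 39495 loci. Those without a gene name (2667 loci, 0.507% to 0.555% of each library's fragments) stayed out of library sizes and tests. A further 16 loci were marked HIDATA in at least 1 library, where the deposited value is 0 and not a measurement, and were left out; 9 of them, among them Thbs1, Ctsb and Fdft1, carry the mark in wild-type libraries only. Loci marked FAIL (1151 in any library) were kept, which left 36812 loci. Where several genes share a locus they cannot be told apart and the locus carries all names. Coordinates are those of the files (mm10, counted from 1). Gene types come from GENCODE M21 on the same build.

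Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust glmQLFit, quasi-likelihood F test), with Benjamini-Hochberg adjusted p under 0.05 as the threshold, as fixed before the data were examined. The common biological coefficient of variation was 0.467. CPM are counts scaled to a common library size with the TMM effective library sizes. Alternatives were DESeq2 1.42.0, limma-voom and limma 3.58.1 on log2(FPKM + 1) or log2(FPKM + 0.1), RLE and upper quartile scaling, no filter, at least 1 CPM in 3 libraries, a non-robust fit, sample quality weights and leaving out each library. Added after seeing the data were fits without FAIL loci, with HIDATA loci at 0, with the macrophage list mean as a covariate, without groups of libraries, and the pooled Stc1 ratio without each library. Gene lists with at least 5 tested members were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry. Genes near Stc1 were tested with a one-sided Fisher's exact test. The test script was tested on simulated data: with no change it called 0 genes, and 4.37% of genes had an unadjusted p under 0.05.

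Named genes were to be Stc1, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and groups that do not overlap, the 5 further ones with the smallest p in each direction, up to 4 members of each list with the smallest p, called genes within 10 Mb of Stc1, and sex-linked genes. As edgeR called 0 genes, those parts named none, and the same rules were applied at an unadjusted p under 0.05, a choice made after the values were seen, as was the naming of genes from the authors' deposited table and of Gm15574. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was 49.9 or more (wild-type replicate 1 against knockout replicate 2) over genes with at least 20 fragments. The macrophage subsets and the classes of RNA without a poly(A) tail were also written after values were seen. A count of 0 is read as allowing up to 3 counts; such floors and 95% intervals cover counting error only.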

Results

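RNA was measured in mouse embryonic fibroblasts, primary cells grown out of embryos, that carried either the normal Stc1 gene or a disrupted one. The labels give both genotypes a C57BL/6 background. There were 6 libraries, 3 from wild-type and 3 from Stc1 knockout cells, and each was prepared with a stranded kit that selects polyadenylated RNA. The deposited files held 71488701, 42509592 and 51153221 estimated fragments for wild-type replicates 1 to 3, and 21882092, 37934030 and 44552311 for knockout replicates 1 to 3. Replicate numbers only name the libraries and do not pair them. The labels do not say whether the libraries of a genotype came from separate embryos or cultures, so the p-values measure only the spread between these libraries. The same 3 index tags were used in both genotypes, so libraries that share a tag cannot have been told apart within one lane; lanes and runs are not given in the sources used here, and their effect was not tested. Xist, the RNA that silences an X chromosome in female cells, lay between 553 and 800.0 CPM (fragments counted, scaled to the same effective library size) in all 6 libraries.

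The targeted gene was examined first. Stc1 encodes stanniocalcin-1, a secreted glycoprotein, and was nearly absent from every knockout library. The files place the gene (XLOC_010371) on the plus strand of chromosome 14 of mm10, from 69029289 to 69041401, where the annotation lists a protein-coding gene with 4 exons. It had 2245, 291 and 368 fragments in the wild-type libraries, or 31.8, 6.82 and 7.62 CPM. The knockout libraries held 6, 0 and 0 fragments, and a count of 0 allows up to 0.08 CPM in knockout replicate 2 and 0.067 CPM in knockout replicate 3. Pooled over libraries, the wild-type level was 310 times the knockout level, with an exact 95% Poisson interval of 142.4 to 846 that covers counting error only. Wild-type replicate 1 held 2245 of the 2904 wild-type fragments, and the ratio was 125 without it, 199 without knockout replicate 2 and 175 without knockout replicate 3. Without knockout replicate 1 no knockout fragment was left, and the wild-type level was at least 493 times a pooled floor of 3 counts. The fitted log2 fold change was -7.72 with a standard error of 1.62. The adjusted p was 0.763 in edgeR's quasi-likelihood test and 3.92e-05 in DESeq2, with a range of 3.92e-05 to 0.982 over all alternatives, and every knockout library lay below every wild-type library. The fragments were counted over the whole locus, and the part of the gene that was disrupted is not given in the sources used here.

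**Figure D1:**
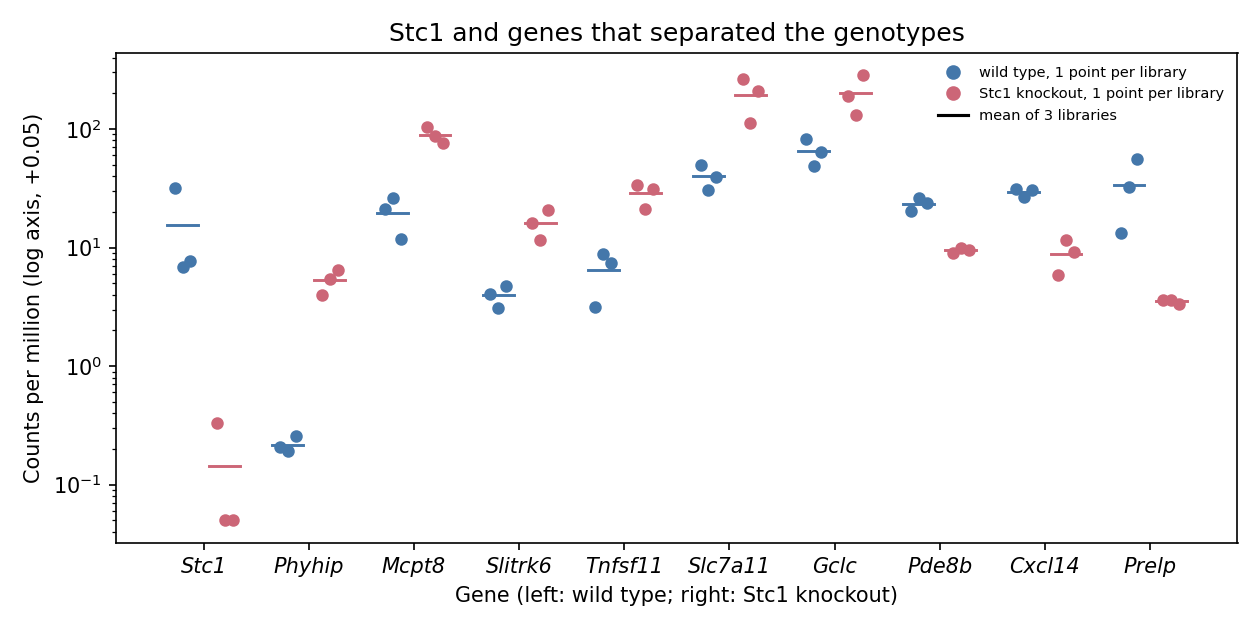
Levels in CPM of Stc1 and 9 other genes in each library, on a log axis after adding 0.05 so that zeros can be drawn; points are libraries, 3 per genotype, and lines are group means. The 9 other genes were picked from those whose groups do not overlap, so the separation is no result of the figure. In each gene shown the knockout libraries lie all above or all below the wild-type libraries, as in Phyhip, where knockout libraries hold 3.90 to 6.41 CPM and wild-type libraries 0.141 to 0.207 CPM.

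The second question was which other genes differ between the genotypes. The gene with the lowest p was Phyhip, a gene known mainly from brain that encodes a protein interacting with phytanoyl-CoA hydroxylase. Phyhip stood at 5.23 ± 1.26 CPM in knockout and 0.168 ± 0.035 CPM in wild-type cells (SD, n = 3 each), a log2 fold change of 4.94 with a standard error of 0.38. Slc7a11, the cystine importer that feeds glutathione synthesis, stood at 195 ± 77.8 CPM in knockout against 39.9 ± 9.74 CPM in wild-type cells. Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, stood at 202 ± 77.2 against 64.8 ± 16.7 CPM. In the other direction, the cyclic AMP phosphodiesterase gene Pde8b stood at 9.48 ± 0.517 CPM in knockout and 23.3 ± 3.0 CPM in wild-type cells.

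None of these genes passed the main test. edgeR's quasi-likelihood test called 0 of 15673 genes higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.194, for Phyhip. At an unadjusted p under 0.05 there were 251 higher and 356 lower genes, or 607 in all, where chance alone would give 784. limma-voom called 0 genes, with 355 higher and 179 lower at an unadjusted p under 0.05. DESeq2 called 29 genes higher and 32 lower, with 1223 at an unadjusted p under 0.05. It tested 23509 genes, without edgeR's filter, so the 1223 cannot be set against the 607 or the 784 expected by chance. limma on log2(FPKM + 1) called 0, with 532 higher and 152 lower at that threshold, and on log2(FPKM + 0.1) it called 1, the predicted gene Gm15574. Without wild-type replicate 1, edgeR gave 1613 higher and 1326 lower genes at an unadjusted p under 0.05; without wild-type replicate 2 it gave 190 and 178, without wild-type replicate 3 it gave 254 and 592, and without knockout replicates 1, 2 or 3 it gave 137 and 140, 196 and 135, or 155 and 115. The share of genes whose groups did not overlap was 10.6%, and chance gives 10%. On simulated counts with the same dispersions, the test called 2% of genes changed 2-fold, 60% of genes changed 4-fold and 88% of genes changed 8-fold. The changed genes, 50 per fold, were drawn only from those with a mean log2 CPM over 2. That simulation also did not contain differences shared by many genes between libraries. Its shares therefore do not give the power on the real libraries, where Stc1 itself was not called by edgeR.

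Of the 61 genes DESeq2 called, 47 had groups that did not overlap, 27 higher and 20 lower in knockout cells, and 4 were on the macrophage marker list. These 4 are not all the calls that vary between libraries as C1qa, one of them, does. Fcrls, Cx3cr1 and Ms4a6b, also called lower, had 0.17, 0.085 and 0.042 CPM in wild-type replicate 1. They had 133, 44.3 and 9.98 CPM in wild-type replicate 2, and 1.60 CPM or less in every knockout library. Genes that DESeq2 called higher included Phyhip, Slc7a11, Gclc, Mcpt8, Slitrk6, Tnfsf11, Foxf2, Rspo3 and Areg. Phyhip, Mcpt8, Slitrk6 and Tnfsf11 lie on chromosome 14 with Stc1, at 1.41, 12.95, 41.72 and 9.25 Mb from it. Mcpt8, a serine protease of basophils, stood at 89.1 ± 13.4 CPM in knockout and 19.6 ± 7.26 CPM in wild-type cells. Tnfsf11, the cytokine RANKL that drives osteoclast formation, stood at 28.6 ± 6.65 against 6.39 ± 2.96 CPM. The Wnt pathway agonist Rspo3 stood at 29.1 ± 6.74 against 12.8 ± 1.67 CPM, and the EGF receptor ligand Areg at 18.0 ± 10.6 against 2.64 ± 1.82 CPM (SD, n = 3 each).

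Genes that DESeq2 called lower included several that encode matrix proteins. Prelp, Fmod and Aspn, which encode small leucine-rich proteoglycans, had log2 fold changes of -3.28, -4.28 and -5.48 in edgeR, with edgeR standard errors of 0.55, 1.24 and 1.64. Abi3bp, an extracellular matrix protein gene, stood at 0.877 ± 0.216 CPM in knockout and 28.9 ± 26.1 CPM in wild-type cells. Itga11, a collagen receptor subunit, stood at 12 ± 10.5 against 118 ± 109 CPM. The chemokine gene Cxcl14 stood at 8.83 ± 2.87 against 29.4 ± 2.51 CPM, and Igfbp6, a binding protein for insulin-like growth factors, at 11.6 ± 2.79 against 35.1 ± 12 CPM. Wild-type replicate 2 held the highest wild-type level of Fmod, Aspn, Abi3bp and Itga11, at 126, 173, 57.0 and 244 CPM.

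The third question was whether genes of a pathway moved together, on 29 gene lists fixed before the data were examined, of which 28 had enough tested genes. camera with a preset correlation of 0.01 placed 8 lists higher and 6 lower in knockout cells at an adjusted p under 0.05. No list passed with an estimated correlation (lowest adjusted p = 0.592) or by fry (lowest adjusted p = 0.574). In the 14 lists that passed, the estimated correlation ran from 0.131 (Hox and positional transcription factors) to 0.974 (macrophage markers), above the preset 0.01 in each. The camera p-values at 0.01 thus treat genes that vary together as nearly independent and overstate the evidence. Over all genes tested, edgeR called 0 members of any list, while DESeq2 called some, among them Slc7a11, Gclc, Cxcl14 and Igfbp6. Adjusted over the list alone, edgeR called 1 member of the oxidative stress list and 1 of the endoplasmic reticulum stress list, Slc7a11 in both, and 1 of the cytokine list, Cxcl14, and 0 members of the other lists. Cxcl14 was lower in knockout cells (log2 fold change -1.73), against the positive median of the cytokine list. Slc7a11 was higher (2.29), against the negative median of the endoplasmic reticulum stress list.

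All 19 tested genes of cholesterol synthesis had negative log2 fold changes, with a median of -0.55. With 1 library left out the median ran from -0.695 (without knockout replicate 1) to -0.37 (without knockout replicate 3). Without wild-type replicate 1 it was -0.46, with 16 of 19 genes negative. The list was lower by camera (adjusted p = 3.07e-08; adjusted p = 0.592 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, stood at 107 ± 10.7 CPM in knockout and 174 ± 32.6 CPM in wild-type cells, and Mvk, the kinase of that pathway, at 27.4 ± 1.5 against 39.7 ± 5.51 CPM. Fdps, the farnesyl diphosphate synthase gene, stood at 19.2 ± 3.40 against 29.0 ± 5.57 CPM. The list mean was lower in every knockout library than in every wild-type library (5.82 ± 0.34 against 6.32 ± 0.20 log2 CPM), for which a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The nearest libraries were knockout replicate 1 at 6.09 and wild-type replicate 2 at 6.12 log2 CPM. Of the 28 lists, 6 had means that separated the genotypes in either direction, among them the stanniocalcin and matrix protease lists, which did not pass camera. Fdft1, a further gene of the pathway, had no usable wild-type value and was left out.

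Of the 34 tested genes of the oxidative stress and NRF2-target list, 29 had positive log2 fold changes, with a median of 0.49 (camera adjusted p = 6.41e-07; adjusted p = 0.592 with an estimated correlation). Besides Slc7a11 and Gclc, the thioredoxin reductase gene Txnrd1 stood at 644 ± 89.5 CPM in knockout against 356 ± 101 CPM in wild-type cells, and the export pump gene Abcc1 at 439 ± 86.7 against 261 ± 71.3 CPM. Wild-type replicate 2 had the lowest level of this list, and without it the median was 0.27.

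Of the 45 tested extracellular matrix genes, 37 had negative log2 fold changes (median -0.70), as did 26 of 29 contractile and myofibroblast genes (median -0.54). Both lists were lower by camera (adjusted p = 3.74e-06 and 7.52e-06; adjusted p = 0.592 for both with an estimated correlation). Postn, which encodes periostin, stood at 565 ± 449 CPM in knockout and 2137 ± 1091 CPM in wild-type cells, and Col6a2, a collagen VI chain gene, at 101 ± 46.4 against 509 ± 517 CPM. Among the contractile genes, Actg2 stood at 39.3 ± 4.08 against 165 ± 141 CPM and Cnn1 at 45.8 ± 5.92 against 150 ± 132 CPM. Smooth muscle and pericyte markers were also lower by camera (12 of 15 negative, median -0.70; adjusted p = 0.0159; adjusted p = 0.592 with an estimated correlation). Without wild-type replicate 2 the medians of these lists were -0.37, -0.22 and -0.25. The smooth muscle call was lost without wild-type replicate 1 or 2, and its median was -1.10 without wild-type replicate 3.

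Cytokine and chemokine genes of the NF-kB list had the largest positive median, 1.18, with 32 of 36 genes positive (camera adjusted p = 5.72e-09; adjusted p = 0.592 with an estimated correlation). Lif, a cytokine of the interleukin-6 family, stood at 333 ± 81.6 CPM in knockout and 60.2 ± 69.7 CPM in wild-type cells. Interferon response genes were positive in 34 of 36 cases with a median of 0.89, hypoxia and glycolysis genes in 34 of 39 with a median of 0.53, and p53 target and senescence genes in 24 of 28 with a median of 0.57. All 3 lists were higher by camera (adjusted p = 3.74e-09, 3.74e-09 and 5.00e-06; adjusted p = 0.592 for each with an estimated correlation). Hif1a, the oxygen-regulated transcription factor gene, stood at 817 ± 211 CPM against 460 ± 77.6 CPM, and the hexokinase gene Hk2 at 234 ± 42.1 against 146 ± 42.4 CPM. Pfkfb4, of the same hypoxia list, went the other way, at 13.2 ± 0.921 CPM in knockout against 22.7 ± 8.57 CPM in wild-type cells. Outside these lists, the matrix metalloproteinase genes Mmp13 and Mmp10 stood at 859 ± 351 and 367 ± 226 CPM in knockout against 104 ± 86.3 and 35.2 ± 49.0 CPM in wild-type cells. Mmp13 is on the list of matrix proteases and their inhibitors, which did not pass camera (adjusted p = 0.388). Wild-type replicate 1 was nearer to the knockout libraries for the cytokine, interferon, hypoxia and p53 lists. Without it their medians were 1.90, 2.13, 0.95 and 1.0, and without wild-type replicate 2 they were 0.80, 0.50, 0.35 and 0.46. The interferon median was 0.59 without knockout replicate 2, and the p53 median 0.37 without wild-type replicate 3 and 0.36 without knockout replicate 3.

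Cell cycle genes were negative in 36 of 40 cases, with a median of -0.88 (camera adjusted p = 3.64e-04; adjusted p = 0.692 with an estimated correlation). Mki67 stood at 61.6 ± 15.9 CPM in knockout and 192 ± 191 CPM in wild-type cells, with 411 CPM in wild-type replicate 2. Without that library the median was 0.03 and the call was lost, and the median was -0.50 with limma-voom, -0.53 with sample quality weights and -0.47 with limma on either FPKM scale. The remaining calls by camera were of Hox and positional transcription factors (median 0.22, adjusted p = 0.0150), MAPK feedback and immediate early genes (median 0.31, adjusted p = 0.0374) and complement and acute phase genes (median 0.91, mean -0.49, adjusted p = 0.0457), all higher. Each had an adjusted p = 0.592 with an estimated correlation, and leaving out 1 library in turn kept the call in 3, 2 and 1 of 6 fits. The Hox call was lost without wild-type replicate 1 or 3 (median 0.23 and 0.03) or knockout replicate 2 (0.08), and its median was 0.39 without wild-type replicate 2. The MAPK call was lost without wild-type replicate 2 or 3 (0.12 and 0.28) or knockout replicate 1 or 2 (0.33 and 0.17). The complement call was lost without wild-type replicate 1 or 2 (1.04 and 0.43) or knockout replicate 1, 2 or 3 (0.90, 1.04 and 0.75), and without wild-type replicate 3 the median was 1.44.

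Macrophage markers, fixed as a list because cultures of embryonic fibroblasts can hold macrophages, varied more between libraries than any other list shown. Their mean was 0.59, 5.99 and 9.12 log2 CPM in wild-type replicates 1 to 3 and 5.26, 2.08 and 2.48 log2 CPM in knockout replicates 1 to 3. The genotypes overlapped (two-sided exact permutation p = 0.6). camera placed the list lower in knockout cells (median -2.82, adjusted p = 0.0189; adjusted p = 0.707 with an estimated correlation), and the call was lost without wild-type replicate 2, wild-type replicate 3, knockout replicate 2 or knockout replicate 3. The median was 0.09 without wild-type replicate 3 and -4.71 without knockout replicate 1. It was -1.18 with limma-voom, -0.52 with sample quality weights (13 of 17 genes negative), and -1.15 and -1.03 with limma on log2(FPKM + 1) and log2(FPKM + 0.1). Without wild-type replicates 2 and 3 and knockout replicate 1, the libraries with the most of these markers, edgeR called 0 genes, with 336 higher and 225 lower at an unadjusted p under 0.05. In that fit the medians were 0.28 for the cytokine, -0.74 for the cholesterol, 0.22 for the oxidative stress, -0.24 for the matrix, -0.21 for the contractile, 0.01 for the interferon, 0.13 for the p53, -0.38 for the cell cycle, -0.09 for the hypoxia, 0.03 for the MAPK, 0.33 for the Hox, 0.99 for the complement and -0.32 for the smooth muscle list. The macrophage list itself had a median of 1.67 in that fit, with 16 of 16 tested genes positive, and the only wild-type library was assumed to vary like the knockout libraries.

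**Figure D2:**
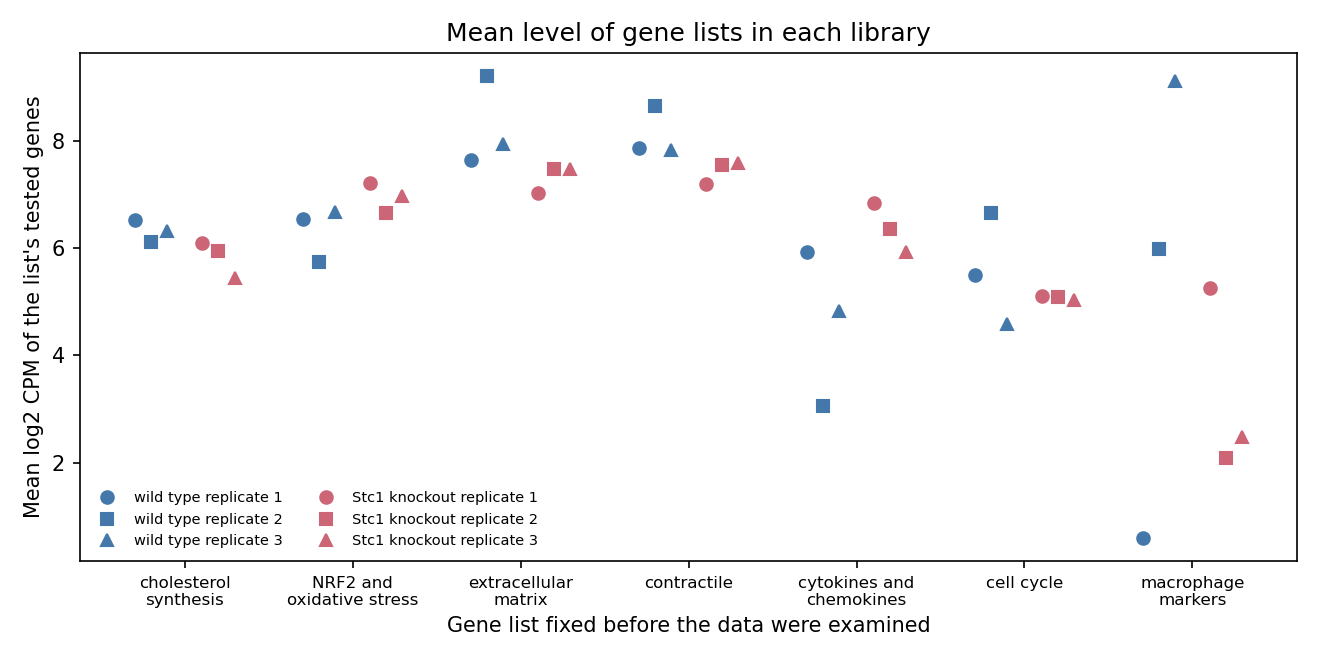
Mean log2 CPM of the tested genes of 7 lists in each library; each point is a library, with colour for genotype and shape for replicate number. Knockout libraries lie below all wild-type libraries for cholesterol synthesis, matrix and contractile genes, and the macrophage marker mean runs from 0.59 to 9.12 among wild-type libraries.

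The other 14 lists did not pass camera. Their median log2 fold changes were -0.08 for stanniocalcin, phosphate and calcium handling genes, -0.21 for endoplasmic reticulum stress, 0.06 for the respiratory chain, 0.31 for matrix proteases and their inhibitors, 0.02 for the insulin-like growth factor axis, 0.16 for imprinted genes and 0.03 for Wnt, BMP and Notch signalling. Among cell type markers the medians were -0.45 for skeletal muscle, -0.65 for endothelium, 0.07 for cartilage and bone, -0.38 for adipocytes, 0.13 for neural cells, 0.19 for epithelium and 0.02 for germ, gonad, kidney and coelomic cells. None of these 14 medians was stable: leaving out 1 library moved each of them by more than 1.5 times. From the lowest to the highest such value, endothelium ran from -1.87 (without knockout replicate 1) to -0.28 (without wild-type replicate 3), adipocytes from -0.93 to 0.40 without the same libraries, and neural cells from -0.62 (without knockout replicate 1) to 0.30 (without knockout replicate 2). Skeletal muscle ran from -0.91 (without knockout replicate 2) to -0.25 (without knockout replicate 3), cartilage and bone from -0.20 (without wild-type replicate 3) to 0.37 (without wild-type replicate 2), epithelium from 0.07 (without knockout replicate 2) to 0.56 (without wild-type replicate 2) and germ, gonad, kidney and coelomic cells from -0.08 (without knockout replicate 1) to 0.28 (without wild-type replicate 1). Endoplasmic reticulum stress ran from -0.29 (without knockout replicate 2) to 0.00 (without wild-type replicate 2), matrix proteases from 0.11 (without knockout replicate 1) to 0.38 (without knockout replicate 2), and imprinted genes from -0.04 (without wild-type replicate 3) to 0.45 (without wild-type replicate 1). The growth factor axis ran from -0.15 (without wild-type replicate 3) to 0.22 (without wild-type replicate 2), Wnt, BMP and Notch signalling from -0.25 (without knockout replicate 3) to 0.15 (without knockout replicate 1), the respiratory chain from 0.00 (without wild-type replicate 2) to 0.13 (without wild-type replicate 3), and the stanniocalcin list from -0.18 (without wild-type replicate 1) to -0.04 (without wild-type replicate 3). The stanniocalcin list had a negative median and a positive direction by camera, and the growth factor, imprinted, Wnt and germ, gonad, kidney and coelomic lists had means of the sign opposite to their medians.

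The fourth question was whether genes near the targeted locus differed more often than others, since sequence of a donor strain can stay around a targeted gene. No gene within 10 Mb of Stc1 was called by edgeR, limma-voom called 0 and DESeq2 called 3 (Phyhip, AC162936.1 and Tnfsf11), while 14 of 130 tested genes there had an unadjusted p under 0.05 in edgeR. That is 10.8%, against 3.81% of the 15542 other genes (odds ratio 3.05; one-sided Fisher's exact test, p = 5.06e-04, a threshold chosen after the values were seen). Phyhip lies 1.41 Mb from Stc1, at 70442803 to 70468832 on chromosome 14. Tnfrsf10b, a death receptor gene 0.74 Mb away, stood at 114 ± 4.41 CPM in knockout and 59.9 ± 20.6 CPM in wild-type cells, and Chmp7, 0.69 Mb away, at 98.8 ± 2.04 against 67.3 ± 13.2 CPM. Adamdec1, a metalloprotease gene 0.47 Mb away, stood at 4.22 ± 1.99 against 0.282 ± 0.404 CPM. Piwil2, a germline small RNA pathway gene 1.34 Mb away, stood at 0.144 ± 0.080 against 1.33 ± 1.08 CPM. Within 5 Mb the share was 8 of 73 genes and within 20 Mb 24 of 261. Without wild-type replicate 1 the odds ratio was 1.41 and the Fisher's exact p was 0.061.

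**Figure D3:**
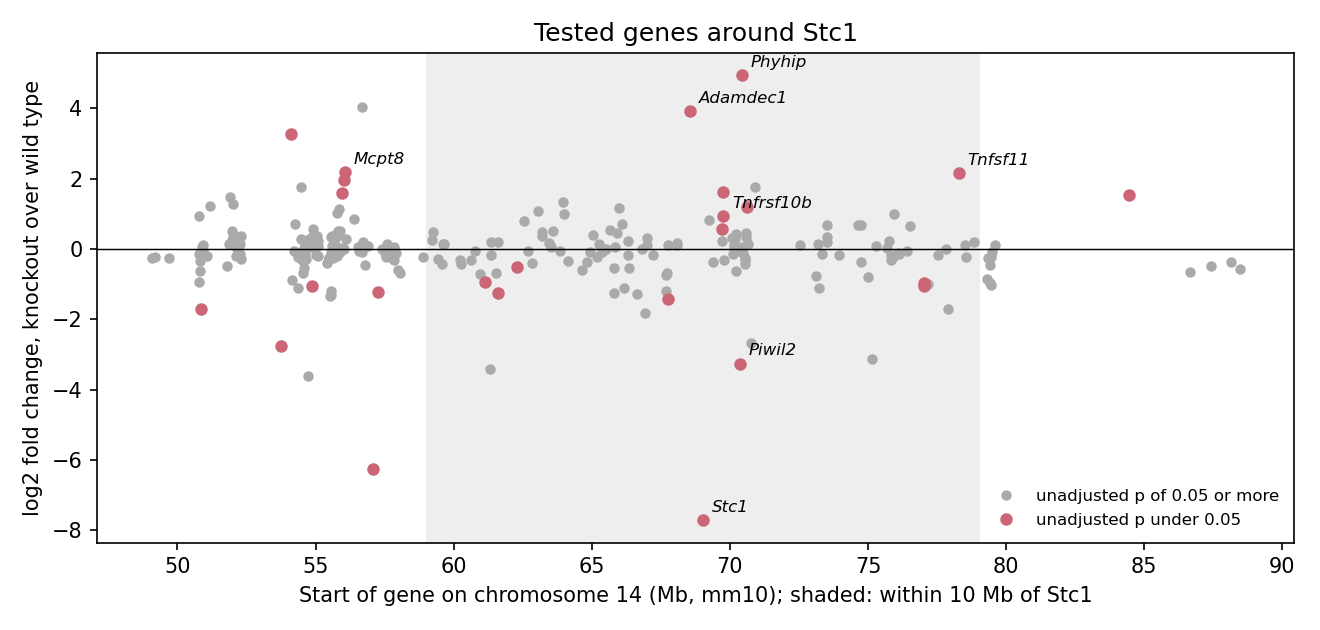
Log2 fold change of knockout over wild-type cells against gene start on chromosome 14 (mm10, Mb) for tested genes within 20 Mb of Stc1; red points have an unadjusted p under 0.05, and the shaded region is within 10 Mb. Phyhip (4.94) and Adamdec1 (3.93) are the highest and Stc1 (-7.72) the lowest of the named points.

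The last comparison was with the authors' deposited table, which compares the same libraries and is not independent evidence. A q-value under 0.05 was given there to 17 genes, 5 higher and 12 lower in knockout cells. Of these, 11 were tested in edgeR, which called 0 of them, with 8 at an unadjusted p under 0.05, and all 11 had the same sign there. The same sign was found for 5 of 10 of these genes tested without wild-type replicates 2 and 3 and knockout replicate 1, and for 13 of 14 without knockout replicate 1. DESeq2 called 4 of them, Stc1, Fcrls, C1qa and Tnmd. Stc1 was listed in the authors' deposited table with a log2 fold change of -7.33 and a q-value of 3.67e-06. The macrophage and complement genes C1qa, C1qb and Fcrls were listed there with log2 fold changes of -8.03, -7.29 and -8.15. Their levels per library overlapped between genotypes: C1qa had 0.255, 90.5 and 810 CPM in wild-type replicates 1 to 3 and 2.91, 0.188 and 0.377 CPM in knockout replicates 1 to 3. Tnmd, the tendon gene tenomodulin, had 0.566, 90.4 and 7.88 CPM against 0.141, 0.322 and 0.177 CPM, and Gjb2, the connexin 26 gene, had 56.4 CPM in wild-type replicate 2 and under 1 CPM in each other library. Mmp13 was listed in the authors' deposited table with a log2 fold change of 3.08. The non-coding RNAs 7SK, RNaseP_nuc and U1 were listed as higher in knockout cells, and knockout replicate 1 alone held 178, 53 and 60.7 CPM of them. Gm14414, also listed as higher, had 12.6 CPM in knockout replicate 2 and 0 CPM in knockout replicates 1 and 3. Among the 17 listed genes, only Stc1, Mmp13 and Tnmd had groups that did not overlap.

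**Figure D4:**
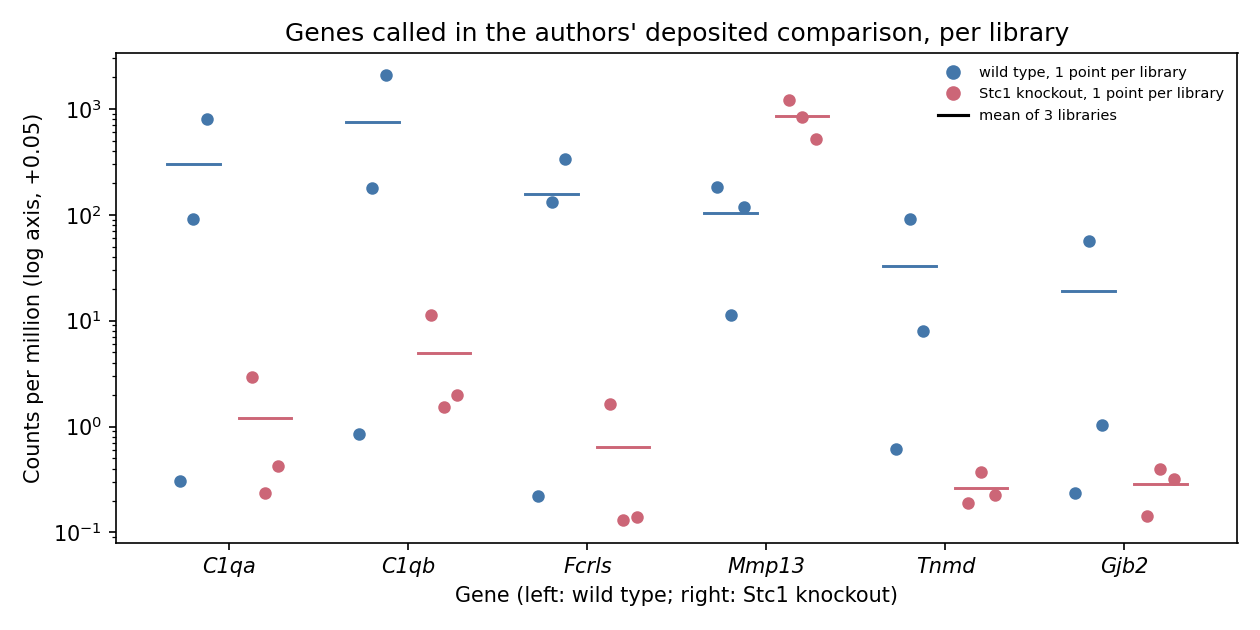
Levels in CPM, on a log axis after adding 0.05, of 6 genes with a q-value under 0.05 in the authors' deposited table; points are libraries, 3 per genotype, and lines are group means. Wild-type replicate 1 lies among the knockout libraries for C1qa at 0.255 CPM, and Mmp13 separates the genotypes.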

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

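These RNAs were not compared as classes above, and the search for them was chosen after 7SK and Lars2 had been seen. Single loci of them do enter the comparisons above. 7SK, RNaseP_nuc and U1 are in the authors' deposited table. A further U1 locus, with 2.21 CPM in knockout replicate 1 and 0 CPM in each other library, is among the 29 genes that DESeq2 called higher. Knockout replicate 1 held several RNAs without a poly(A) tail at levels over 3 times those of any wild-type library. In that library 7SK RNA reached 181.5 CPM, RNase P RNA 62.4 CPM, RNase MRP RNA 82.1 CPM, spliceosomal RNAs 104.51 CPM and signal recognition particle RNA 0.94 CPM. Lars2, a locus listed as holding repeats that resemble ribosomal RNA, reached 11145 CPM there against 45.5 to 70.0 CPM in wild-type libraries. The other knockout libraries held 0.97 and 0.91 CPM of 7SK RNA and 51.4 and 71.2 CPM of Lars2. Small nucleolar RNAs did not share the pattern, at 284 CPM in knockout replicate 1 and 217 to 505 CPM in wild-type libraries. No biological explanation was tested, since the signal belongs to a single library.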

How the results depend on the processing

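The fits with HIDATA loci at 0, the odds ratio at an unadjusted p and the fits without several libraries were chosen after seeing the data. DESeq2 called 29 genes higher and 32 lower, called Stc1 at a log2 fold change of -7.53, called 3 genes near Stc1 and 4 genes that the authors' deposited table also called; the cause was not tested. limma on log2(FPKM + 0.1) called 1 gene higher. With HIDATA loci kept at 0, edgeR called 7 loci higher and 1 lower; 7 of these 8 are those loci, whose zeros are the cause, and the other is Phyhip; 3 of the 8 (Phyhip, Ctsb and Fdft1) lie within 10 Mb of Stc1. camera with an estimated correlation and fry each called 0 lists, and leaving out 1 library gave 10 to 14 lists by camera and 0 genes by edgeR. The odds ratio near Stc1 ran from 1.41 (without wild-type replicate 1) to 5.07 (without wild-type replicate 2) when 1 library was left out. Without wild-type replicates 2 and 3 and knockout replicate 1, C1qa, C1qb and Gjb2 changed sign, to 0.16, 1.08 and 0.73, and so did the macrophage list (16 of 16 tested genes positive, median 1.67). The other settings called 0 genes by edgeR or limma, and the Stc1 level kept its direction in all, between -6.63 and -12.56 with 1 library left out; -12.56 is from the fit without knockout replicate 1, where no knockout fragment is left, so it depends on the prior count and is no bound. Over the other settings Stc1 ran from -1.87 with limma on log2(FPKM + 1) and -4.53 on log2(FPKM + 0.1), where the added constant shrinks it, to -13.66 without 3 libraries, which again leaves no knockout fragment. With sample quality weights the medians were -0.41 for the smooth muscle, 0.37 for the Hox and 0.48 for the MAPK list; the cytokine median was 1.83 with limma on log2(FPKM + 0.1), and with the macrophage covariate the p53 median was 0.37 and the macrophage median 0.71. Of 917 values for 44 other named genes, 893 kept direction and side of the threshold, 21 passed it and 3 changed sign. As the main fit called 0 genes, keeping the side of the threshold means only that a gene stayed uncalled, so this count is no measure of robustness. Depth limits Stc1 in knockout cells, where only 6 fragments were seen.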

Other observations

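Tests of neighbouring windows and of the macrophage covariate were fixed before their results were seen; the comparison of macrophage subsets, the share of genes near Stc1 at an unadjusted p and the count of splits were chosen afterwards. Within the macrophage markers, C1qa, C1qb, C1qc and Mrc1 stood apart from pan-leukocyte genes such as Tyrobp and Ptprc. The log2 ratio of these 4 genes to 7 pan-leukocyte genes was -1.43, 1.12 and 1.17 in wild-type replicates 1 to 3 and -3.63, -3.08 and -3.44 in knockout replicates 1 to 3. The difference was -3.67 with a standard error of 0.87, and a two-sided exact permutation test gave p = 0.1, the smallest it can give. The genes were grouped after some of their values had been seen. Wild-type replicate 1 correlated most with knockout replicates 2 and 3 across genes (Pearson r of log2 CPM 0.985 and 0.973) and less with wild-type replicates 2 and 3 (0.911 and 0.874).

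No gene within 10 Mb of Stc1 was called by edgeR, but 14 of 130 had an unadjusted p under 0.05, a higher share than elsewhere (odds ratio 3.05; 1.41 without wild-type replicate 1, Fisher's exact p = 0.061), and clustering of neighbouring genes is a technical explanation for that share. Only 0.62% of 14953 windows of the same size elsewhere reached the share seen around Stc1, against a median of 3.23%. The windows were centred on tested genes and overlap, so neighbouring ones are not independent and those that reached the share may lie in few regions. In the main fit, the one compared, this argues only weakly against clustering alone. The highest share, 17.2%, lay on chromosome 13. Donor-strain sequence kept around the targeted gene, an effect of the altered locus on its neighbours, and a real effect of losing Stc1 stay open, and none of them was tested.

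The oxidative stress list had a positive and the cholesterol synthesis list a negative median log2 fold change; both passed camera only with the preset correlation (adjusted p = 0.592 for each with an estimated correlation, and 0.574 by fry), and macrophage share may be a cause of these medians. With the macrophage list mean as a covariate the median log2 fold change of the oxidative stress list was 0.59 (0.49 without it; 28 of 34 members positive) and that of the cholesterol list -0.51 (-0.55 without it; 19 of 19 negative). Both stayed over the bound set beforehand. Without wild-type replicates 2 and 3 and knockout replicate 1, the cholesterol median was -0.74 and the oxidative stress median 0.22. That fit keeps 1 wild-type library, replicate 1, which had the highest cholesterol list mean of the 6 libraries (6.53 log2 CPM). Its cholesterol median therefore cannot tell macrophage share from variation between libraries. For the cholesterol list the covariate value alone argues against macrophage share as the whole cause. The oxidative stress value of 0.22 is under the bound set for the covariate fit, and the median was 0.27 without wild-type replicate 2 alone. For that list macrophage share is therefore not decided. Knockout of Stc1 and other differences between the cultures stay open.

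The real split of the 6 libraries called 0 genes and the highest other split 0, so all 10 of the 10 splits reach that number by construction, and the comparison decides nothing. The splits are also too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 607 genes and the highest other, wild-type replicate 1 with knockout replicates 2 and 3 against the rest, gave 1918. Further splits gave 1036, 779 and 620, and the remaining ones 318 or fewer. This points to a structure of the libraries that does not follow genotype. Wild-type replicate 1 and knockout replicates 2 and 3 had the lowest macrophage list means, 0.59, 2.08 and 2.48 log2 CPM, against 5.26 to 9.12 in the others.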
